A study of Oryza sativa with 6 samples.

How the data were processed

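RNA sequencing of 5-week-old seedlings of rice cultivar Pusa Basmati 1 was represented by 6 libraries in 3 groups of 2, namely wild type, OsRDR3 over-expression and OsRDR3 knock-down. Total RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. Cufflinks 2.2.1 and Cuffdiff were used by the authors, per the submitters' processing notes. Loci carry Cuffmerge numbers and the nearest BGIOSGA transcript, per the file headers. The aligner, the genome build and the version of Cuffdiff are not given in the sources used here.

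There were 2 files, each a table of the authors' comparison of a transgenic group with wild type. The FPKM values, fragment numbers scaled by transcript length and library size, were computed by the authors as 1 pooled value per group and locus, per the file headers. The deposited log2 fold change is the log2 of the transgenic over the wild-type FPKM with no pseudocount, which was checked by recomputing it. The deposited p-values and q-values come from the authors' test, and the p-values were multiples of 5e-05 up to 0.05. The lowest q-values were 0.000868 in the table of libraries labelled knock-down, shared by 912 loci, and 0.00105 in the over-expression table, shared by 721. No locus was listed at 0, and columns of single libraries that could not be assigned numbered 0. The tables hold no counts, so depth per library and counting error are unknown and no confidence interval was computed. Because groups are pooled, no spread between replicates can be given for any value.

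The number of tests behind each q-value was recovered from the ratio of q to p, which equals the number of tests over the rank. The number for which most p levels gave whole ranks, within a relative tolerance of 3e-06, was 17618 for the libraries labelled knock-down (89.7% of levels, next best 7.17%) and 17596 for over-expression (91.1%, next best 24.4%). The 4341 and 4295 listed loci were therefore 24.6% and 24.4% of those tested. The ranks imply 4620 and 4571 loci at p of at most 0.05, so 279 and 276 loci are not analysed here, of which 179 and 190 have an implied q under 0.05. Counts of called loci are lower bounds for this reason.

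A locus was called at the authors' q under 0.05. The design written before the data were examined foresaw a Fisher exact test of called against uncalled loci per gene list, which cannot be made without p-values for the unlisted loci. It was replaced by a 2-sided Fisher exact test of direction, higher against lower, among called loci inside and outside a list with at least 3 called loci. Benjamini-Hochberg adjustment was over the 8 lists tested in each comparison. A short list whose called loci all move in the commoner direction of its table cannot pass this test. The median log2 fold change of a list with at least 5 listed loci was placed among 10000 random lists of the same size, matched in 10 bins of mean FPKM. Percentiles and tests across loci describe these libraries, as genes are not independent replicates. Gene Ontology terms from the tables with at least 10 called loci were tested for direction in the same way, which was decided after the data were seen. Directions of list calls were compared between the tables with Fisher's exact test, adjusted over 7 lists. Also decided after the data were seen, they were compared with random called sets of the same sizes from each table by exact enumeration. At p under 0.05 before adjustment, this found 40 of 40 shifted and 0 of 160 random simulated pairs of sets. The shifted sets moved toward the rarer direction of each table.

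Fixed before the data were examined were 15 lists with 245 genes, namely silencing, photosynthesis, heat shock, defence, diterpenoid phytoalexin, clock, flowering time, floral, root, iron acquisition, phosphate starvation, cell cycle, drought and abscisic acid, jasmonate, and senescence. They were matched by gene symbol, and 27 genes were matched in this way in either table. Loci with the protein name RNA-dependent RNA polymerase were added to the silencing list. The floral and root lists stand for other tissues. A further 20 keyword lists were matched to protein names, covering disease resistance, receptor kinase, WRKY, heat shock, transposon, histone, ribosomal protein, photosystem and light harvesting, peroxidase, glutathione transferase, cytochrome P450, terpene synthase, aquaporin, expansin, seed storage, MYB, NAC, F-box, AP2/ERF and lipid transfer. A protein name other than uncharacterized was given for 766 and 790 listed loci and a symbol for 215 and 209, so lists cover few of their members. The reference table of rice genes matched 0 of 6884 BGIOSGA identifiers and was not used.

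Named genes followed a rule fixed in advance. It took every RNA-dependent RNA polymerase, the 8 largest rises and 8 largest falls among called loci with a symbol or protein name and at least 1 FPKM in the higher group, up to 4 called members of each list (or up to 2 of highest FPKM where none was called), and up to 5 loci called in both comparisons in the same and in opposite directions. It also provided for loci listed at 0, of which there were 0. Members of Gene Ontology terms named outside this rule are said to be chosen after their values were seen.

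The overlap between comparisons was set against independent lists, n1 × n2 / N over 17596 loci, and against 100 simulated draws of unchanged groups sharing the wild-type libraries, with a correlation of 0.5 between z values. Simulated calls were the top loci in the observed number per table and direction, while simulated listing required p of at most 0.05. Fold changes were also centred on the median of the listed loci. Alternatives planned before the data were examined were a q of 0.01, an absolute log2 fold change of at least 1, a minimum of 1 FPKM, Benjamini-Hochberg adjustment over the listed loci, omission of loci at 0 or with several gene identifiers, centring, and pseudocounts of 1 and 0.1. Chosen after seeing the data were the submitters' own regulation column, omission of structural RNA loci, restriction to numbered chromosomes, a correlation without the polymerase locus, and centring of the loci called in both.

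The recovery of the number of tests, the direction tests, the random-list percentiles and the overlap simulation were tested on simulated data. The number of tests was recovered in 20 of 20 simulated tables for each comparison. The direction test found 40 of 40 shifted sets in each comparison, and 1 of 160 unshifted sets for the libraries labelled knock-down and 0 of 160 for over-expression. The shifted sets held up to 40 called loci, mostly from the rarer direction of their table. How often the test finds shorter lists or shifts in the commoner direction was not examined. Random lists fell in either outer tail of the percentiles in 6 of 80 cases for the libraries labelled knock-down and 2 of 80 for over-expression. Run without a shared control, the simulation of overlap gave 49.8 shared loci where independent lists give 50. With a shared control it gave the built-in correlation of 0.5 between z values, but its overlap counts were not checked against a known number. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.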

Results

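RNA sequencing was carried out on 5-week-old seedlings of the indica rice cultivar Pusa Basmati 1. The 6 libraries fell into 3 groups of 2, which were wild type, plants over-expressing OsRDR3, and plants labelled as OsRDR3 knock-down. OsRDR3 belongs to the RNA-dependent RNA polymerases, enzymes that copy RNA into double-stranded RNA. Each transgenic group was set against wild type in a separate table of FPKM values, with 1 pooled value per group and locus. The labels do not state whether replicates came from separate plants. The p-values are those of the authors' Cuffdiff test, and the pooled values do not show the spread behind them. At most they reflect variation between these libraries, which may be technical. Sequencing depth per library is unknown because the values are FPKM without read counts. The table for the libraries labelled knock-down listed 4341 loci and that for over-expression 4295, all with an unadjusted p of at most 0.05, and other loci are not analysed here.

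The targeted polymerase was examined ahead of the comparisons because it checks the labels. BGIOSGA002194, annotated as an RNA-dependent RNA polymerase, lies on chromosome 1 from 5687015 to 5701037, on a genome build not given in the sources used here. The tables do not pair this locus with the name OsRDR3. In the authors' deposited table for over-expression it stood at 0.198 FPKM in wild type and 58.7 FPKM in the transgenic plants, a 296-fold rise with q = 0.00105. In the authors' deposited table for the libraries labelled knock-down it rose from 0.190 to 69.5 FPKM, 366-fold, with q = 0.000868. Wild type is near 0, so both folds are uncertain, and with a pseudocount of 1 the log2 fold change was 5.89 in the libraries labelled knock-down and 5.64 in over-expression. The rise in the libraries labelled knock-down goes against the knock-down label, if the locus is the target. A second polymerase locus, BGIOSGA009008 on chromosome 2 from 32711899 to 32717317, rose from 4.40 to 7.63 FPKM in the libraries labelled knock-down in the authors' deposited table, with q = 0.000868. These were the 2 loci of the RNA silencing list matched in the libraries labelled knock-down, and BGIOSGA002194 was the 1 matched in over-expression. Adjusted over the list alone, 2 and 1 loci were called. Because the level of this locus, if it is the target, goes against the label, directions below are given for libraries labelled knock-down and not for a loss of the gene.

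The comparison of the libraries labelled knock-down with wild type asks which transcripts differ in plants under that label. Transcripts for photosynthesis were lower in the libraries labelled knock-down. Of the 19 listed photosystem and light-harvesting loci, 16 fell and 0 rose, and the median log2 fold change of the 19 was -1.80. The chlorophyll a-b binding protein locus BGIOSGA004351 fell from 1031 to 182 FPKM, a log2 fold change of -2.50, in the authors' deposited table. The drought-responsive transcription factor SNAC1 rose from 3.17 to 28.8 FPKM in the authors' deposited table, and of the called peroxidases 11 rose and 13 fell. These directions come from libraries in which the polymerase locus, if it is the target, goes against the label.

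Across the genome, 2358 loci passed q under 0.05 in Cuffdiff's test, of which 766 were higher and 1592 were lower in the libraries labelled knock-down. At least 2-fold differences were found for 505 higher and 760 lower loci. The median log2 fold change over all listed loci was -0.58, and after centring on it 895 loci were higher and 1462 lower.

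The photosystem and light-harvesting group was lower beyond the general excess of lower loci, with p = 0.0024 and q = 0.0192 in a 2-sided Fisher's exact test of direction among called loci. All 16 called loci stayed lower after centring. Their group's median lay below all 10000 random lists matched on mean FPKM, at percentile 0. In the authors' deposited table, chlorophyll a-b binding protein loci BGIOSGA026003, BGIOSGA035064 and BGIOSGA025944 had log2 fold changes of -2.19, -2.13 and -1.93, each with q = 0.000868. The fixed photosynthesis list had 1 matched locus, PSAH, a subunit of photosystem I, which fell from 490 to 137 FPKM in the authors' deposited table. Adjusted over the list alone, that 1 locus was also called.

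Gene Ontology terms were tested for direction in the same way, a test chosen after the data were seen. Of 232 terms with at least 10 called loci, 53 passed q under 0.05, 42 of them toward lower and 11 toward higher loci. In the chloroplast thylakoid membrane term 107 loci fell and 2 rose (q = 2.19e-14), and centring gave 105 and 4. In the photosynthesis term 70 fell and 1 rose (q = 1.07e-09), with the same split after centring. All 29 called loci of chlorophyll biosynthesis fell (q = 0.000247), of which 25 stayed lower after centring. The starch biosynthesis term had 39 lower and 2 higher loci, the carotenoid biosynthesis term 33 and 1, and photorespiration 19 and 0, which centring changed to 33 and 8, 28 and 6, and 18 and 1. Examples chosen after their values were seen include glutamyl-tRNA reductase (BGIOSGA031606), the enzyme at the start of chlorophyll precursor synthesis, which fell from 101 to 16.3 FPKM in the authors' deposited table. Magnesium chelatase subunit ChlH (BGIOSGA012530) fell from 244 to 78.8 FPKM and the small subunit of Rubisco (BGIOSGA018498) from 4307 to 1193 FPKM in the authors' deposited table. Phytoene synthase (BGIOSGA020499), which starts carotenoid synthesis, fell from 24.1 to 9.44 FPKM in the authors' deposited table.

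The 11 terms shifted toward higher loci in the libraries labelled knock-down included cell wall, glycosyl hydrolysis, extracellular, defense, stress, acyl transfer and ADP binding terms. Enzymes hydrolysing O-glycosyl compounds had 47 higher and 21 lower loci (q = 1.67e-08), which centring changed to 48 and 20, and the extracellular region term had 20 and 6 (q = 5.52e-05). The defense response term had 21 higher and 12 lower loci (q = 0.002) and the plant-type cell wall term 21 and 16 (q = 0.0151), which became 22 and 11, and 24 and 13, after centring. Narrower defense terms did not pass. Defense response to bacterium had 13 higher and 40 lower loci (q = 0.42) and to fungus 9 and 14 (q = 0.506). For incompatible interactions the counts were 1 and 14 (q = 0.136), and with fungus 8 and 5 (q = 0.111). Peroxidases, which act in the cell wall and in detoxification, were divided, with 11 of 32 listed loci rising and 13 falling. The direction test gave q = 0.302 for them, while their median of 0.87 lay at percentile 99.99 among matched lists. The 32 listed loci split into 17 higher and 15 lower, from -2.02 to 5.24, so this median does not stand for a common shift. The peroxidase loci BGIOSGA021076 and BGIOSGA007858 rose from 0.451 to 17.1 FPKM and from 0.406 to 7.40 FPKM in the authors' deposited table.

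The 6 listed loci of the defence list were all higher, and 3 rose, whether adjusted over all loci or adjusted over the list alone. Their median lay at percentile 98.7, but the direction test did not pass (Fisher's exact p = 0.0342, q = 0.0684). The class IV chitinase gene Cht4, whose product degrades chitin, rose from 6.39 to 20.9 FPKM in the authors' deposited table. WRKY71 rose from 1.60 to 9.50 FPKM and WRKY53 from 13.4 to 20.2 FPKM in the authors' deposited table, both transcription factors of the defence response. Among 7 listed WRKY loci 3 rose and 0 fell, with q = 0.0684 in the exact test and percentile 97.2. WRKY45-2 had a log2 fold change of 1.27 in the authors' deposited table. The drought and abscisic acid list had 3 listed loci, and all 3 rose (exact q = 0.0684), also when adjusted over the list alone, with 1 called at q under 0.01. Besides SNAC1, these were SalT and the abscisic acid catabolic gene ABA8ox1, with log2 fold changes of 1.93 and 1.42 in the authors' deposited table.

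The called flowering and clock genes were lower in the libraries labelled knock-down. MADS14, a MADS-box gene of the floral transition, fell from 6.18 to 0.520 FPKM with q = 0.0167 in the authors' deposited table, and MADS18 had a log2 fold change of -0.77. These were the 2 listed members of the flowering list, 2 called when adjusted over the list alone and 0 at q under 0.01. The clock genes PRR37 and PRR73 fell by 0.87 and 0.59 on the log2 scale in the authors' deposited table. These were the 2 listed clock loci, 2 called when adjusted over the list alone and 1 at q under 0.01. CPS2, an ent-copalyl diphosphate synthase of phytoalexin synthesis and the 1 listed locus of both the diterpenoid list and the terpene synthase keyword, fell from 3.31 to 0.653 FPKM in the authors' deposited table. The jasmonate biosynthesis gene AOC, 1 of 1 listed, fell by 0.82 on the log2 scale in the authors' deposited table. Adjusted over the list alone, 1 diterpenoid and 1 jasmonate locus were called. Of 2 listed iron acquisition loci, the nicotianamine synthase gene NAS2 rose from 0.618 to 4.02 FPKM in the authors' deposited table, and adjusted over the list alone 1 was called. The phosphate gene SPX1 was the 1 listed of its list and did not pass, with q = 0.124 in the authors' deposited table and 0 loci called when adjusted over the list alone.

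Listed histone loci were also below wild type, 9 of 9, and 4 fell. Their median of -1.16 lay at percentile 0.7. The direction test could not separate the 4 called members from other called loci (exact q = 0.355), as most called loci were lower and 4 were too few to pass. After centring, 2 of the 9 listed loci turned higher and the 4 called loci stayed lower, and 2 were called at q under 0.01. Histone H2A.5 (BGIOSGA010990) fell from 8.56 to 2.02 FPKM in the authors' deposited table, at a locus that holds several gene identifiers. H2B.9, H2B.5 and H2A.2 had log2 fold changes of -1.47, -1.37 and -1.16 in the authors' deposited table. Reads of near-identical histone copies could be divided between loci, so each single copy is uncertain.

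Other groups held few called loci. Of 12 listed ribosomal protein loci 2 rose and 1 fell (exact q = 0.331), with 0 called at q under 0.01, and the 1 that fell, the plastid gene rps14, turned higher after centring. Of 9 listed lipid-transfer protein loci 2 rose and 6 fell (exact q = 1), which became 4 and 4 after centring. Of 2 listed disease resistance loci 1 rose and 1 fell, and 2 of 2 listed F-box loci rose, 1 of them called at q under 0.01. The heat shock protein gene HSP81-1, the glutathione transferase gene GSTZ5 and the MYB gene MYBS2, each the 1 listed member of its keyword, fell by 0.72, 1.33 and 1.45 on the log2 scale in the authors' deposited table. The 1 listed cytochrome P450 locus was ABA8ox1, which rose but was not called at q under 0.01. The 1 listed expansin, EXPA4, had q = 0.0652 in the authors' deposited table and did not pass.

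Among annotated loci named by size of change, large rises besides the polymerase and the peroxidases were a carboxypeptidase (BGIOSGA020441) and an F-box protein (BGIOSGA008785), with log2 fold changes of 4.84 and 4.20 in the authors' deposited table. A RING-type ubiquitin ligase (BGIOSGA030660), the peroxygenase PXG and malate synthase (BGIOSGA014839), an enzyme of the glyoxylate cycle, followed with 3.98, 3.91 and 3.70 in the authors' deposited table. After MADS14, the largest falls were a xyloglucan endotransglucosylase/hydrolase (BGIOSGA014404) at -3.52 and a glycosyltransferase (BGIOSGA004012) at -3.05 in the authors' deposited table. The serine/threonine kinases BGIOSGA002159 and BGIOSGA000786 followed at -2.98 and -2.91 in the authors' deposited table. A WAT1-related protein (BGIOSGA011443), an ammonium transporter (BGIOSGA008408) and a lipoxygenase (BGIOSGA006958) had log2 fold changes of -2.69, -2.64 and -2.64 in the authors' deposited table. These orders hold without a pseudocount. With a pseudocount of 1, BGIOSGA002159 was lowest of these falls at -2.53, before MADS14 at -2.24, BGIOSGA014404 at -1.88 and BGIOSGA004012 at -1.13. Among the rises, BGIOSGA020441 went to 2.35 and BGIOSGA030660 to 1.37.

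The comparison of over-expression with wild type asks which transcripts differ in plants made to over-express OsRDR3. Most called loci were higher in the over-expression libraries. All called loci matched to the histone, peroxidase and cell cycle lists were higher, numbering 7, 22 and 4, while all 6 called photosystem and light-harvesting loci were lower. All 17 listed histone loci were higher, with a median log2 fold change of 1.86. The direction test could not set the called ones apart from other called loci (exact q = 0.401), as 7 higher and 0 lower were too few to pass. Of 35 listed peroxidase loci, 22 rose and 0 fell. Histone H2A.5 (BGIOSGA010990) rose from 8.91 to 79.5 FPKM in the authors' deposited table.

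Over all loci, 2211 passed q under 0.05 in Cuffdiff's test, 1626 higher and 585 lower in over-expression. At least 2-fold differences were found for 960 higher and 116 lower loci. The median log2 fold change of listed loci was 0.67, and centring on it moved the split from 73.5% higher to 62.5% higher, with 1381 higher and 829 lower loci.

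The histone median lay at percentile 100 among matched lists. After centring, 16 of the 17 listed histone loci stayed higher, as did the 7 called, of which 3 were called at q under 0.01. Besides H2A.5, H2B.2 rose from 4.60 to 44.0 FPKM and H3.2 (BGIOSGA017977) had a log2 fold change of 4.27 in the authors' deposited table. H2AXb and H2B.9 had log2 fold changes of 2.70 and 1.86 in the authors' deposited table. The H3.2 and H2A.5 loci hold several gene identifiers, and division of reads between near-identical copies makes each copy uncertain.

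Of the cell cycle list 4 loci were matched by symbol and all 4 rose, also when adjusted over the list alone. A split of 4 higher and 0 lower could not pass the direction test (exact q = 0.661). The 4 loci encode subunits of the MCM helicase, which opens DNA for replication. In the authors' deposited table MCM3, MCM5, MCM6 and MCM7 had log2 fold changes of 1.69, 1.73, 1.62 and 2.25, at transgenic levels from 0.992 to 1.58 FPKM. At q under 0.01 only 1 of the 4 was called. Chosen after their values were seen, PCNA (BGIOSGA009238), the sliding clamp of DNA polymerase, rose from 4.20 to 11.1 FPKM and MCM2 (BGIOSGA035270) had a log2 fold change of 1.74 in the authors' deposited table. Both names are on the fixed cell cycle list, but these loci were not matched to it by symbol and are not among the 4. Other examples chosen after their values were seen were a kinesin-like protein (BGIOSGA019825), an alpha tubulin (BGIOSGA035072) and Actin-1 (BGIOSGA013463), with log2 fold changes of 1.98, 1.44 and 1.72 in the authors' deposited table.

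Peroxidases were higher beyond the general excess of higher loci (Fisher's exact p = 0.0023, q = 0.00919), with a median of 1.53 at percentile 100, and centring left 19 higher and 3 lower. Peroxidase loci BGIOSGA033360 and BGIOSGA020118 had log2 fold changes of 3.68 and 3.31 in the authors' deposited table. Of 35 listed ribosomal protein loci 21 rose and 1 fell (exact p = 0.0146, q = 0.039), at percentile 93.0, but their median of 0.63 was below that of all listed loci and centring gave 13 higher and 9 lower. At q under 0.01, 10 of these loci were called. The 60S protein L13 gene (BGIOSGA010380) rose from 41.5 to 93.4 FPKM in the authors' deposited table.

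The photosystem and light-harvesting group had 12 listed loci, all lower, of which 6 fell and stayed lower after centring (exact p = 0.000337, q = 0.00269), with a median of -0.76 at percentile 0. BGIOSGA004351 fell from 1075 to 490 FPKM and the light-harvesting locus BGIOSGA013052 had a log2 fold change of -0.77 in the authors' deposited table. PSAH, the 1 listed locus of the fixed photosynthesis list, fell from 511 to 292 FPKM in the authors' deposited table, and adjusted over the list alone 1 locus was called.

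Of 233 Gene Ontology terms with at least 10 called loci, 85 passed q under 0.05 in the direction test chosen after the data were seen, 52 toward lower and 33 toward higher loci. The chloroplast thylakoid membrane term had 53 lower and 6 higher loci (q = 4.09e-23), the photosynthesis term 33 and 5 (q = 1.27e-13), and chlorophyll biosynthesis 14 and 0 (q = 8.15e-08). Centring gave 55 and 4, 35 and 3, and 14 and 0. Glutamyl-tRNA reductase (BGIOSGA031606), chosen after its values were seen, fell from 105 to 60.0 FPKM in the authors' deposited table. The plant-type cell wall term had 43 higher and 0 lower loci (q = 1.53e-05), which centring changed to 39 and 4, and the extracellular region term 31 and 1 (q = 0.0043), changed to 30 and 2. The nucleolus term had 73 higher and 1 lower loci (q = 4.21e-08), which centring changed to 41 and 32. The cytosolic ribosome term had 53 and 2 (q = 9.84e-05), changed to 36 and 19, and vesicle-mediated transport 27 and 0 (q = 0.00153), changed to 14 and 13. A coatomer beta subunit (BGIOSGA034416), chosen after its values were seen, rose from 9.05 to 18.7 FPKM in the authors' deposited table.

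**Figure D1:**
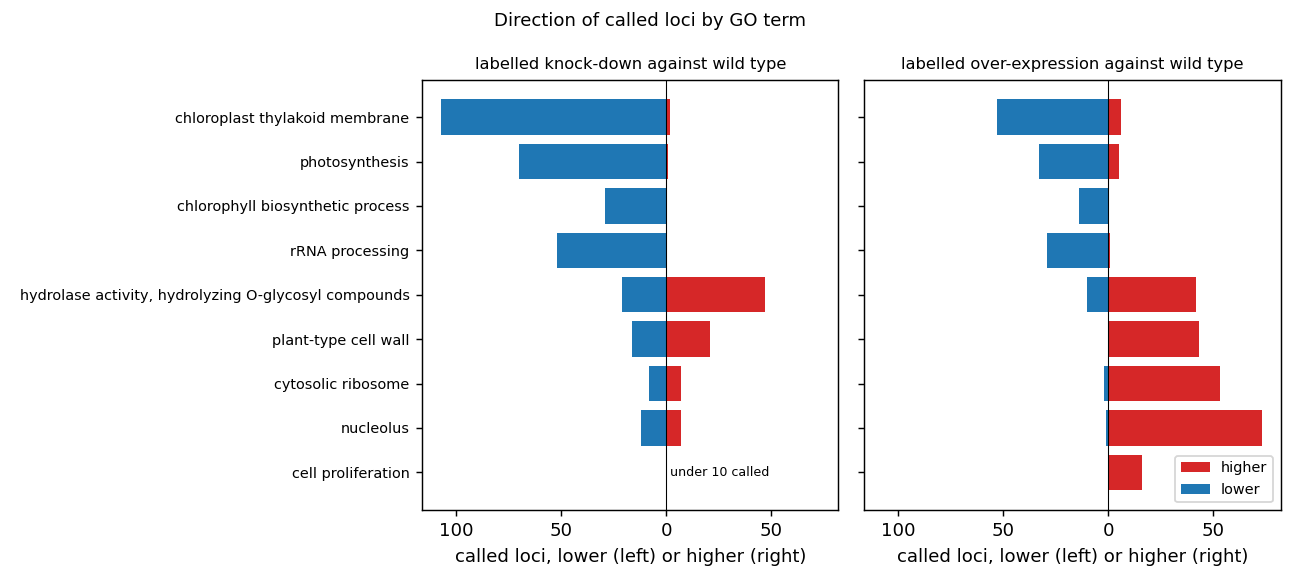
Bars give the number of loci called at q under 0.05 that were lower (left of 0) or higher (right of 0) than wild type in selected Gene Ontology terms, for libraries labelled knock-down (left panel) and over-expression (right panel). Thylakoid membrane loci lay mostly on the lower side in both, with 107 and 53 lower loci, while 73 nucleolus loci lay on the higher side in over-expression, of which 41 stayed higher after centring.

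Of 5 listed defence loci, all higher, 3 rose (exact q = 0.661, percentile 96.1), and centring turned 1 uncalled locus lower. WRKY71, WRKY76 and Cht4 had log2 fold changes of 1.80, 1.67 and 1.13 in the authors' deposited table. Adjusted over the list alone, 3 defence loci were called. Of 6 listed WRKY loci 4 rose and 0 fell (exact q = 0.661), and centring turned 1 uncalled locus lower. By Gene Ontology the defense response term did not pass (13 higher and 7 lower, q = 0.562), nor did defense response to fungus (11 and 6, q = 0.531). Defense response to bacterium was shifted toward lower (17 higher and 15 lower, q = 0.042). The drought list had 4 listed loci, 2 of which rose, and adjusted over the list alone 2 were called. SNAC1 rose from 3.30 to 10.9 FPKM and ABA8ox1 had a log2 fold change of 1.69 in the authors' deposited table. ABA8ox1 was also among the 2 cytochrome P450 loci that rose of 3 listed, 1 of them called at q under 0.01. The clock list had 2 listed loci, of which PRR37 fell by 0.67 on the log2 scale in the authors' deposited table, and adjusted over the list alone 1 was called, but 0 at q under 0.01. CPS2, the 1 listed diterpenoid and terpene synthase locus, fell by 0.95 on the log2 scale in the authors' deposited table. The iron regulator IRO2, 1 of 1 listed, fell by 0.77 on the log2 scale, and the root metal transporter NRAMP5, 1 of 1 listed of the root list, rose from 0.366 to 2.54 FPKM in the authors' deposited table. Adjusted over the list alone, 1 diterpenoid, 1 iron and 1 root locus were called.

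Of 6 listed lipid-transfer protein loci 3 rose and 1 fell (exact q = 1). The 1 listed disease resistance locus fell but was not called at q under 0.01, and neither of 2 listed F-box loci passed. The heat shock, floral and senescence lists had 0 matched loci in either comparison, as did the keywords receptor kinase, transposon, aquaporin, seed storage, NAC domain and AP2/ERF. The NAC keyword does not match the protein name of SNAC1, which was listed in both tables under the drought list. Lists with 0 matched loci in the libraries labelled knock-down only were root and cell cycle. Lists with 0 in over-expression only were flowering, phosphate and jasmonate and the keywords heat shock, glutathione transferase, expansin and MYB. Members with no match were not counted in their lists, even where their loci are named elsewhere.

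Named by size of change, a beta-hexosaminidase locus (BGIOSGA019873) on chromosome 5 rose from 0.183 to 8.64 FPKM in over-expression in the authors' deposited table. A pectinesterase (BGIOSGA014585), a 3-ketoacyl-CoA synthase of long-chain fatty acid synthesis (BGIOSGA003684) and the transporter ABCG5 (BGIOSGA012359) had log2 fold changes of 3.91, 3.81 and 3.41 in the authors' deposited table. A xyloglucan endotransglucosylase/hydrolase (BGIOSGA008858) had 3.36 in the authors' deposited table. The falls were smaller, with the glycosyltransferase BGIOSGA004012 at -1.82 and the xyloglucan endotransglucosylase/hydrolase BGIOSGA014404 at -1.53 in the authors' deposited table. The photosystem I assembly gene ycf4, the kinase BGIOSGA000786 and a UMP-CMP kinase (BGIOSGA022162) had log2 fold changes of -1.45, -1.45 and -1.42 in the authors' deposited table. A potassium transporter (BGIOSGA010387), a histone deacetylase (BGIOSGA037104) and the kinase BGIOSGA002159 had -1.23, -1.21 and -1.20 in the authors' deposited table.

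Setting both comparisons side by side asks whether plants under the opposite labels differ from wild type in opposite ways. Of 682 loci called in both, 608 (89.1%) moved the same way and 74 in opposite directions. Thylakoid membrane loci called in both numbered 48, of which 47 were lower in both, and of the 33 photosynthesis loci called in both 32 were lower in both. Histones H2A.5 and H2B.9 fell in the libraries labelled knock-down and rose in over-expression.

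In detail, 270 loci were higher in both, against 70.8 for independent lists and 291 in a simulation of unchanged groups sharing the same wild-type libraries. The simulation took as many top loci as were called in each table and direction, and so did not require them to pass a p. With p of at most 0.05 required instead, 162 simulated loci were listed in both, against 1714 observed and 1060 for independent lists. All simulated loci were unchanged, so far fewer passed this p per table than the 4341 and 4295 listed. The simulated number is therefore small by construction and is not comparable with the other numbers. Of the loci listed in both, 84.8% moved the same way, against 99.9% in the simulation. Lower in both were 338 loci, against 52.9 for independent lists and 233 simulated top loci. Lower in the libraries labelled knock-down and higher in over-expression were 66 loci, against 147 and 9.25, and the reverse held for 8, against 25.5 and 0.33. The tables give wild type as 1 pooled value without values per library, so the controls were not split between the comparisons. Part of the excess over independent lists may come from the shared controls, and for loci higher in both all of it may. Across the 1714 loci listed in both, the Pearson correlation of log2 fold changes was 0.763 (simulated 0.976), the Spearman correlation 0.756 and the covariance 1.41 (simulated 1.13), and genes are not independent replicates. Selection of loci at p of at most 0.05 acts on observed and simulated values alike and limits what their difference shows. The simulated errors were drawn from the observed fold changes and p-values of these loci, with 1 error per locus used for both comparisons. The simulated correlation and covariance are therefore not independent of the observed values, and no conclusion is drawn from them.

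**Figure D2:**
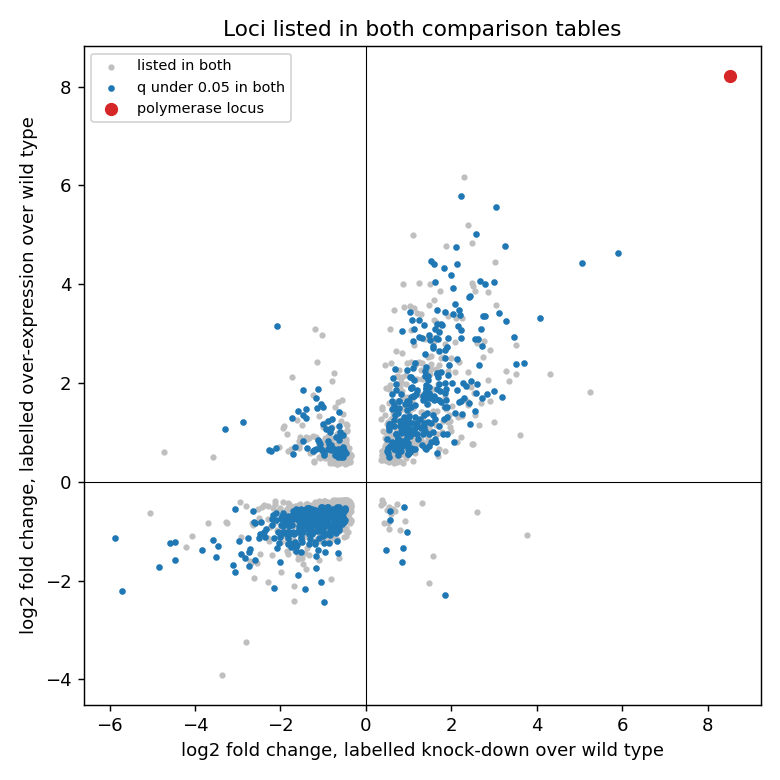
Each point is a locus listed in both tables, with its log2 fold change over wild type in libraries labelled knock-down (x axis) and in over-expression (y axis). Blue points had q under 0.05 in both comparisons, 608 of these 682 loci lie in the same-direction quadrants, and the red point is the polymerase locus at 8.52 and 8.21 in the authors' deposited table.

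Among the 338 loci lower in both, the median log2 fold change was -1.20 in the libraries labelled knock-down and -0.77 in over-expression, and 279 were further down in the former. This order depended on centring, which gave medians of -0.62 and -1.44 and left 34 further down in the libraries labelled knock-down. The medians subtracted, -0.58 and 0.67, are those of loci listed at p of at most 0.05. They depend on how many listed loci rose or fell and are not a measure of scaling. Among the 270 higher in both, the medians were 1.37 and 1.64 with 96 further up in the libraries labelled knock-down, which centring turned to 1.95 and 0.97 with 229. Wild-type FPKM was 1.04 times as high in the over-expression table, as a median over loci listed in both. Large same-direction rises besides the polymerase were found at BGIOSGA017285 (log2 fold changes 5.91 and 4.63), BGIOSGA005685 (5.05 and 4.42) and BGIOSGA032538 (3.26 and 4.78) in the authors' deposited table. The beta-hexosaminidase locus BGIOSGA019873 had 3.05 and 5.56 in the authors' deposited table. Opposite directions besides the histones were found at BGIOSGA008937 (-2.87 and 1.21), BGIOSGA015174 (-3.30 and 1.07) and BGIOSGA021412 (1.86 and -2.29) in the authors' deposited table.

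Called histone loci split into 0 higher and 4 lower in the libraries labelled knock-down and 7 and 0 in over-expression (Fisher's exact p = 0.00303, q = 0.0106 over 7 groups). Peroxidases split into 11 higher and 13 lower against 22 and 0 (exact p = 2.94e-05, q = 0.000206). Called loci as a whole differ in the same way between the tables. Against random called sets of the same sizes, a test chosen after the data were seen, neither group passed after adjustment. The exact p was 0.0432 (q = 0.178) for histones and 0.328 (q = 0.515) for peroxidases. The histone split was already the most extreme possible in its direction, so a larger difference could not have been seen with so few called loci. The other 5 groups compared, defence, WRKY, ribosomal, photosystem and lipid-transfer, had q of 0.403 or more between the tables and 0.178 or more against random sets. Structural RNA loci, which carry no protein-coding gene, were listed 21 times in the libraries labelled knock-down, with 10 called higher and 3 lower, and 31 times in over-expression, with 15 and 3. Centring changed the over-expression counts to 14 and 4. Of 14 listed in both tables, 11 were higher in both, 3 lower in both and 0 opposite. Of all loci listed in both 84.8% moved the same way, and the simulation of unchanged groups gave the same sign for 99.9% of its loci listed in both.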

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

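The tests of the explanations and of the differences between the comparisons in this part were chosen only after the result was seen, while the overlap of calls, the gene lists and the percentiles were planned. The directions of called loci differed between the comparisons for histones (Fisher's exact p = 0.00303) and for peroxidases (exact p = 2.94e-05). The split of all called loci into higher and lower also differed (exact p = 8.43e-175), with 32.5% higher in the libraries labelled knock-down and 73.5% higher in over-expression. These tests run across loci, which are not replicates. The histone and peroxidase differences were not shown to go beyond this general split, as against random called sets of the same sizes from each table they gave exact q = 0.178 and 0.515. For histones the exact p before adjustment was 0.0432, with the most extreme split possible in its direction. The test therefore leaves the question open for them. What drew attention in each case was the difference between the transgenic groups under the same contrast with wild type. Because the level of the polymerase locus, if it is the target, goes against the knock-down label, these differences are not read here as loss against gain of the gene.

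The polymerase locus stood 366-fold above wild type in the libraries labelled knock-down in the authors' deposited table, a fold that rests on a wild-type value near 0 (log2 fold change of 5.89 with a pseudocount of 1). An exchange of the labels between both transgenic groups is argued against only if no construct transcripts were counted at the locus. It then needs a level not above wild type in the libraries labelled over-expression, where the locus was 296-fold higher in the authors' deposited table. With transcripts of a knock-down construct counted there, an exchange would not need such a level and cannot be decided. Over-expressing plants under the knock-down label may account for it, as the fold was 1.24 times that of over-expression, but this value does not separate it from other sources. Transcripts of a knock-down construct that carries part of the gene may also be counted at the locus, and the 366-fold rise in the authors' deposited table comes with no value per exon to decide. Both remain open.

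Of the listed histone loci 4 of 9 were called lower in the libraries labelled knock-down and 7 of 17 called higher in over-expression. The direction tests did not pass (exact q = 0.355 and 0.401), and so few called loci could not have passed them. Scaling by 1 factor moves all loci of a table alike, while the histone medians lay at percentiles 0.7 and 100 of matched lists. Among listed loci this argues against scaling as the whole cause but does not exclude it. The matched lists were drawn only from loci at p of at most 0.05, a filter that scaling can itself affect, and histone copies are not independent. Reads shared between histone copies could shift values between loci, and the summed FPKM of the listed loci was 0.631 and 2.03 times wild type, but copies without a listed value keep this open. More dividing cells in the over-expression seedlings remain open. All 4 cell cycle genes matched by symbol rose, with 1 called at q under 0.01. The direction test (exact q = 0.661) cannot show whether this exceeds the general excess of higher loci. A split of 4 higher and 0 lower could not pass it. The terms cell proliferation and microtubule-based movement passed (each 16 higher and 0 lower, q = 0.031), while DNA replication (17 and 1, q = 0.11) and cytokinesis (10 and 0, q = 0.132) did not. With so few called loci cytokinesis could not have passed, and its split was unchanged by centring, so its failure does not bear on the question. Fewer dividing cells in the libraries labelled knock-down remain open, since 0 loci of the cell cycle list were matched by symbol there. Only 215 listed loci carry a symbol, so this does not show that cell cycle genes were unchanged.

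Loci called in both comparisons mostly moved the same way. The shared wild-type libraries may give part of this or, for loci higher in both, all of it. The top loci of simulated unchanged groups, taken in the observed numbers, gave 233 lower in both against 338 observed. For loci higher in both they gave 291 against 270 observed, so no excess over the simulation was seen there. With p of at most 0.05 required, 162 were listed in both against 1714. Unchanged groups list far fewer loci per table, so that difference does not bear on the question, and simulated values exclude nothing. A difference in RNA or library preparation between wild type and transgenic samples could act alike in both. Of the 14 structural RNA loci listed in both tables, 0 moved in opposite directions. However, 84.8% of all loci listed in both also moved the same way, and shared controls alone gave the same sign for 99.9% of simulated ones. The structural RNA loci therefore do not decide. An effect of polymerase over-expression common to both transgenic groups was not tested and stays open too. These explanations cannot be told apart because both comparisons use the same wild-type libraries.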

How the results depend on the processing

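The centring, thresholds, filters and pseudocounts were planned, and the regulation column, the omission of structural RNA loci, the restriction to numbered chromosomes and the correlation without the polymerase were chosen after seeing the data. For the libraries labelled knock-down the 2358 called loci became 1408 at q of 0.01, 1265 with an absolute log2 fold change of at least 1, and 4338 with adjustment over the listed loci alone, which leaves out the tests of unlisted loci. For over-expression the 2211 became 1144, 1076 and 4293. In all other alternatives the counts stayed within 1.5 times, from 1857 to 2358 and from 1606 to 2211, and lower loci outnumbered higher ones for the libraries labelled knock-down and the reverse for over-expression in each. Omitting loci at 0 removed none. Centring moved the share of higher loci from 73.5% to 62.5% in over-expression and from 32.5% to 38.0% in the libraries labelled knock-down. It also turned the order of loci called in both, chosen after seeing the data, from 279 of 338 lower loci further down in the libraries labelled knock-down to 34, and from 96 of 270 higher loci further up to 229, since the medians subtracted differ in sign. The polymerase log2 fold change fell to 5.89 and 7.91 with pseudocounts of 1 and 0.1 in the libraries labelled knock-down and to 5.64 and 7.62 in over-expression, since wild type is near 0. Loci called in both numbered 307 at q of 0.01 and 249 with an absolute log2 fold change of at least 1, from 682. The correlation was 0.737 with a pseudocount of 1 and from 0.751 to 0.758 otherwise. At q of 0.01 calls in the gene lists went from 83 to 57 and from 84 to 56, leaving in the libraries labelled knock-down 0 of 2 flowering, 1 of 2 clock, 1 of 3 drought, 2 of 4 histone, 0 of 3 ribosomal, 0 of 1 P450 and 1 of 2 F-box calls, and in over-expression 0 of 1 clock, 1 of 4 cell cycle, 0 of 1 disease resistance, 3 of 7 histone, 10 of 22 ribosomal and 1 of 2 P450 calls. Of 132 fold changes of named loci, 84 moved by over 0.1 with a pseudocount of 1 and 44 with 0.1, and 0 reversed. No paired analysis was possible because the columns carry no replicate values, and the planned analyses without each replicate and with a replicate block were not run for that reason. Depth is unknown, so its limit on low loci cannot be stated.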

Other observations

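The term tests in this part were chosen after the data were seen. In over-expression the microtubule term had 29 higher and 1 lower loci (q = 0.00642), and 26 and 4 after centring. Protein kinase activity had 123 higher and 24 lower loci in over-expression (q = 0.0129), and 116 and 31 after centring. The counts were 56 and 96 in the libraries labelled knock-down (q = 0.42), which centring changed to 65 and 87. Of all called loci 73.5% were higher in over-expression and 32.5% in the libraries labelled knock-down, so these counts do not show opposite shifts. A difference between the groups was not tested for this term. Of other kinase terms in over-expression, kinase activity stood at 29 higher and 21 lower loci, shifted toward lower (q = 0.0436), and protein serine/threonine kinase activity at 78 and 24 (q = 0.683). Cell proliferation had 16 higher and 0 lower loci in over-expression (q = 0.031), and histone H3-K9 methylation 19 and 0 (q = 0.0217), which centring changed to 15 and 1, and 17 and 2. Golgi loci were 46 higher and 4 lower (q = 0.00719), and 34 and 16 after centring.

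The methylerythritol 4-phosphate pathway term of isoprenoid precursor synthesis had 44 lower and 1 higher loci in the libraries labelled knock-down (q = 8.83e-06) and 30 and 0 in over-expression (q = 1.06e-16), and centring gave 37 and 8, and 30 and 0. The rRNA processing term had 52 lower and 0 higher loci (q = 4.23e-08) and 29 and 1 (q = 6.25e-15), and centring gave 48 and 4, and 30 and 0. Divalent metal ion transport had 14 lower and 0 higher loci in the libraries labelled knock-down (q = 0.034). The ADP binding term had 19 higher and 15 lower loci there (q = 0.0274) and 8 and 10 in over-expression (q = 0.0377), and centring gave 20 and 14, and 8 and 10. The difference between the groups was not tested. Phytoene synthase (BGIOSGA020499), chosen after its values were seen, fell by 0.53 on the log2 scale in over-expression in the authors' deposited table. Many terms share loci, so these tests are not independent of each other.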
